A study of Mus musculus with 24 samples.

How the data were processed

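Total RNA of 24 samples was hybridized to Illumina mouse Ref-8 version 2 arrays after labelling as biotinylated cRNA with the Ambion MessageAmp kit, per the labels' protocols. The deposited scanner table holds the mean bead intensity of 25697 probes per array on the linear scale, summarised in GenomeStudio gene expression module 1.8.0 without normalization or background subtraction, per the file headers. The same deposited table gives a detection p-value for each probe and array against that array's negative controls, and the number of beads. The authors also deposited a matrix of intensity values that are linear, background-subtracted (28.4% of probes are negative on each array) and equal between arrays in median (23.4 to 23.5) and 75th percentile (294.9 to 297.5). How that matrix was normalized is not given in the sources used here. It was used only as an alternative source of values. Bead standard errors were not used here.

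Samples were grouped by the cell line in their labels, giving 8 groups of 2 to 4 arrays. Arrays of a group correlated with r = 0.941 to 0.994, and 0 pairs held identical values. The intensity was background-corrected with normexp using detection p-values, quantile normalized and placed on the log2 scale (limma 3.58.1 neqc, offset 16, in R 4.3.3). Probes with a detection p under 0.01 on at least 2 arrays were kept, 12693 in all. Probes were named through a RefSeq gene table of assembly GRCm38.p6, with 16938 matched by Entrez ID, 4666 by accession, 1422 by synonym and 2295 by current symbol, and 376 keeping the symbol in the file. The build behind the probe positions is not given in the sources used here, so no coordinates are printed. The probe with the highest mean stood for each of 9228 genes. Of 292 genes called between aggressive and indolent lines with a second kept probe, 284 had every other probe changing in the same direction.

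All 24 arrays were fitted in 1 limma model with a mean for each group, and contrasts were tested with limma's two-sided moderated test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Log2 fold changes are given with the SE of the fit. Intensities of a group are given as mean and SD over its arrays. Where a line on the lower side of a gene's comparison had no array with a detected probe, its level was placed at the detection floor of its arrays (5.80 to 6.58 on the log2 scale) and the fold is given as "at least". The fitted log2 change of such a gene depends on the offset. Gene lists written beforehand (18 with at least 5 measured members) were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and limma's fry were alternatives. Counts of called members were also made with the adjustment over the list alone. The comparisons, the rules for naming genes and most alternatives were chosen before the data were examined. The genes themselves were then picked by their results. The largest changes were ranked among called genes whose arrays did not overlap between the groups. Gene models without a gene name, such as Riken clones, were passed over. The Hoxb genes were followed as a cluster, and Hoxa5 and Hoxa7 were named, outside these rules. Fits with runs of 8 columns, without the third run and with array weights were added afterwards.

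Alternatives were no background correction, a normexp offset of 50, scaling to the 75th percentile, the authors' deposited values, other filters on dim probes, the mean of a gene's probes, eBayes with trend and robust settings, only the groups compared, no fold minimum, a replicate block, a term for the samples with late submitter numbers, arrays or lines left out, line means and the line as a random block. A slide block was not run, because slides are not named in the sources used here. Of the 14 values of single MOC1 arrays that stood apart by Dixon's test, 1 is not reported here. The procedure was tested on simulated data with 200 of 9228 genes changed in each of 10 comparisons. Of the changes of 1.5 on the log2 scale, 70 to 98% were recovered, and at least 97% of those of 3. At most 3.66% of calls were false, and the raised list was called in 10 of 10 comparisons. The simulated genes were drawn independently of each other. They held neither the axes along which arrays of a line differ nor the correlation among members of a list. These rates therefore need not hold for the real arrays.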

Results

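Gene expression was measured on 24 Illumina mouse Ref-8 version 2 arrays, 1 per RNA sample, in 7 mouse oral carcinoma cell lines and in primary oral keratinocytes of C57BL/6 mice grown in the same medium. Per the labels, the indolent lines were MOC1 (n = 4 arrays), MOC22 (n = 3) and MOC23 (n = 3). The aggressive lines were MOC2 and its derivatives MOC2-7 and MOC2-10 (n = 3 each), with lymph node metastasis on the labels of all 3 and lung metastasis in addition for MOC2-10. LN (n = 3) was grown from a nodal metastasis that a MOC2 tumour formed, and its growth was labelled as not done. The normal oral keratinocytes (OK) had 2 arrays. Between 9267 and 10999 of 25697 probes were detected per array, with a mean of 32.2 to 40.95 beads per probe and a median intensity of 149 to 175.5. After removal of undetected probes, 9228 genes were tested. The number of arrays per group limits the precision. Nothing in the labels says that arrays of a line came from separate cultures, so p-values measure the spread between arrays, which may be technical.

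The genotype label was checked first. Cxcr3, the chemokine receptor gene given as inactivated in the MOC2 lines, was detected on 0 of 24 arrays, wild-type keratinocytes included, and its lowest detection p on any array was 0.256. The probe therefore checked no label. LN carries a wild-type label although it was derived from the MOC2 tumour. Cd44, which encodes a hyaluronan receptor used as a marker of carcinoma cell subsets, was detected on every array. Its mean log2 intensity was 12.96 ± 0.20 (SD, n = 3) in MOC22, 11.23 ± 0.49 (n = 4) in MOC1 and 10.39 ± 0.41 (n = 3) in MOC23. In MOC2 it was 12.13 ± 0.12 (n = 3), in MOC2-7 11.67 ± 0.27 (n = 3), in MOC2-10 12.07 ± 0.16 (n = 3), in LN 12.31 ± 0.47 (n = 3) and in the keratinocytes 12.47 ± 0.40 (n = 2). Cd44 differed by 0.43 ± 0.16 (log2, SE) between aggressive and indolent lines, under the 2-fold minimum.

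The lines of MOC2 descent resembled each other most. Across the 9228 genes, group means correlated with r = 0.990 between MOC2-7 and MOC2-10, 0.979 between MOC2 and MOC2-10 and 0.978 between MOC2 and LN. MOC1 and MOC2 correlated with r = 0.938, above every pair of indolent lines (0.925 to 0.931), so this measure did not order MOC1 by its growth label. The keratinocytes were farthest from MOC2-10, with r = 0.853. These correlations are across genes, which are not independent replicates. The first principal component held 35.9% of the variance and separated the MOC2 family from the other arrays, and the second held 13.6%.

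**Figure D1:**
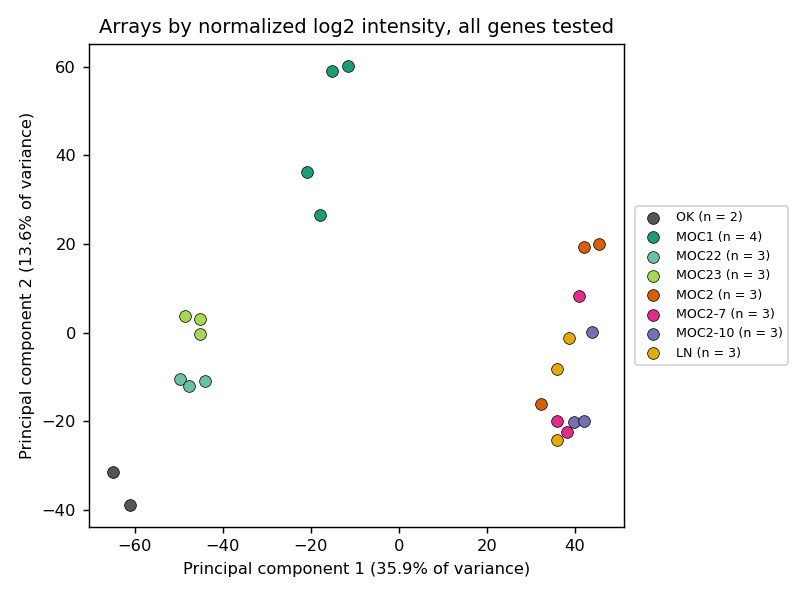
Principal component scores of the 24 arrays over 9228 genes, with 35.9% of the variance on the x axis and 13.6% on the y axis; each point is an array, coloured by line. The 12 arrays of MOC2, MOC2-7, MOC2-10 and LN lie on the right, the indolent lines and the keratinocytes on the left.

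The series was designed to compare aggressive with indolent lines. Trp63, Krt5 and Col17a1, genes of basal keratinocytes, had no detected signal in the aggressive lines. A fold is given as at least a value where a line on the lower side had no array with detected signal. Trp63, which encodes the transcription factor p63 of basal epithelium, had a mean log2 intensity of 11.93 in the indolent lines (10 of 10 arrays detected) and was detected on 0 of 9 aggressive arrays. Its log2 fold change was -7.13 ± 0.13 (SE, adjusted p = 1.56e-19), a level at least 53.04-fold lower. Krt5, the type II keratin of basal cells, changed by -8.01 ± 0.18 (at least 107.8-fold, adjusted p = 5.95e-18) and was detected on 0 of 9 aggressive arrays. Col17a1, a hemidesmosome collagen that anchors basal cells, changed by -7.76 ± 0.11 (at least 82.75-fold, adjusted p = 1.52e-21), also with 0 of 9 arrays detected. Krt14, the keratin that pairs with Krt5, changed by -0.87 ± 0.15, under the 2-fold minimum, with a mean log2 intensity of 14.78 ± 0.33 (SD, n = 3) in MOC2, 13.91 ± 0.25 (n = 3) in MOC2-7 and 14.96 ± 0.25 (n = 3) in MOC2-10, beside 15.49 ± 0.10 (n = 4) in MOC1, 15.54 ± 0.03 (n = 3) in MOC22 and 15.22 ± 0.59 (n = 3) in MOC23. The levels in the indolent lines lie near the top of the intensity scale, so this change may be understated.

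In all, 1154 of 9228 genes were called between aggressive and indolent lines, 523 higher and 631 lower in the aggressive lines, and 527 without background correction. For 401 of these, all 9 aggressive arrays lay on one side of all 10 indolent arrays. Over all 9228 genes this share was 5.32%, where chance gives 0.00217% only if arrays of a line count as independent. For the means of the 3 lines on each side, the share was 28%, where chance gives 10% for lines that are independent, and the aggressive lines share 1 parent. Without the 2-fold minimum 4015 genes passed, and the balance turned to 2255 higher and 1760 lower. Among genes with a gene name whose arrays did not overlap, the largest decrease was at Krt90, an epithelial keratin, with -9.25 ± 0.15 (at least 250.1-fold, adjusted p = 1.4e-20). Acta2, smooth muscle actin, changed by -7.77 ± 0.32 (at least 115.9-fold), Gpx2, a glutathione peroxidase of epithelia, by -7.67 ± 0.23 (at least 157.2-fold), and Dmkn, a secreted protein of differentiating epidermis, by -6.55 ± 0.21 (at least 72.38-fold). Krt6b, a keratin of activated keratinocytes, Crabp2, a retinoic acid binding protein, and Slpi, a secreted protease inhibitor, changed by -6.38 ± 0.37 (at least 58.35-fold), -6.10 ± 0.22 (at least 33.74-fold) and -6.02 ± 0.24. Trp53, the tumour suppressor gene of p53, changed by -3.80 ± 0.14 (adjusted p = 1.2e-14), with signal on 9 of 9 aggressive arrays.

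Among genes higher in the aggressive lines, ranked in the same way, the largest increase was at Cldn6, a tight junction claudin of embryonic epithelium, with 6.96 ± 0.17 (SE, adjusted p = 1.44e-17). Its mean log2 intensity in MOC2 was 14.53 ± 0.17 (SD, n = 3), beside 10.16 ± 0.53 (n = 3) in MOC23 and 6.32 ± 0.31 (n = 4) in MOC1. Krt19, a keratin of simple epithelium, was higher by 6.41 ± 0.14 (at least 43.55-fold), but MOC1 carried it at 11.73 ± 0.46 (SD, n = 4) and MOC22 and MOC23 on 0 of 3 arrays each. Cd55, which protects cells from complement, was higher by 6.00 ± 0.19 (at least 55.44-fold), and Nkx2-3, a homeobox gene of gut mesoderm and pharynx, by 5.35 ± 0.13 (at least 36.08-fold). Muc1, an apical membrane mucin, was higher by 4.76 ± 0.21 and detected on 9 of 9 aggressive and 0 of 10 indolent arrays, so its level was at least 14.52-fold higher. Tspan8, a tetraspanin linked to cell motility, Tph1, an enzyme of serotonin synthesis, and Rhox5, an X-linked homeobox gene, were higher by 5.21 ± 0.19 (at least 19.9-fold), 4.78 ± 0.21 (at least 14.64-fold) and 4.59 ± 0.15. F2r, a thrombin receptor, and Il5ra, the interleukin 5 receptor chain, were higher by 4.47 ± 0.28 and 4.38 ± 0.34 (at least 14.03-fold).

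**Figure D2:**
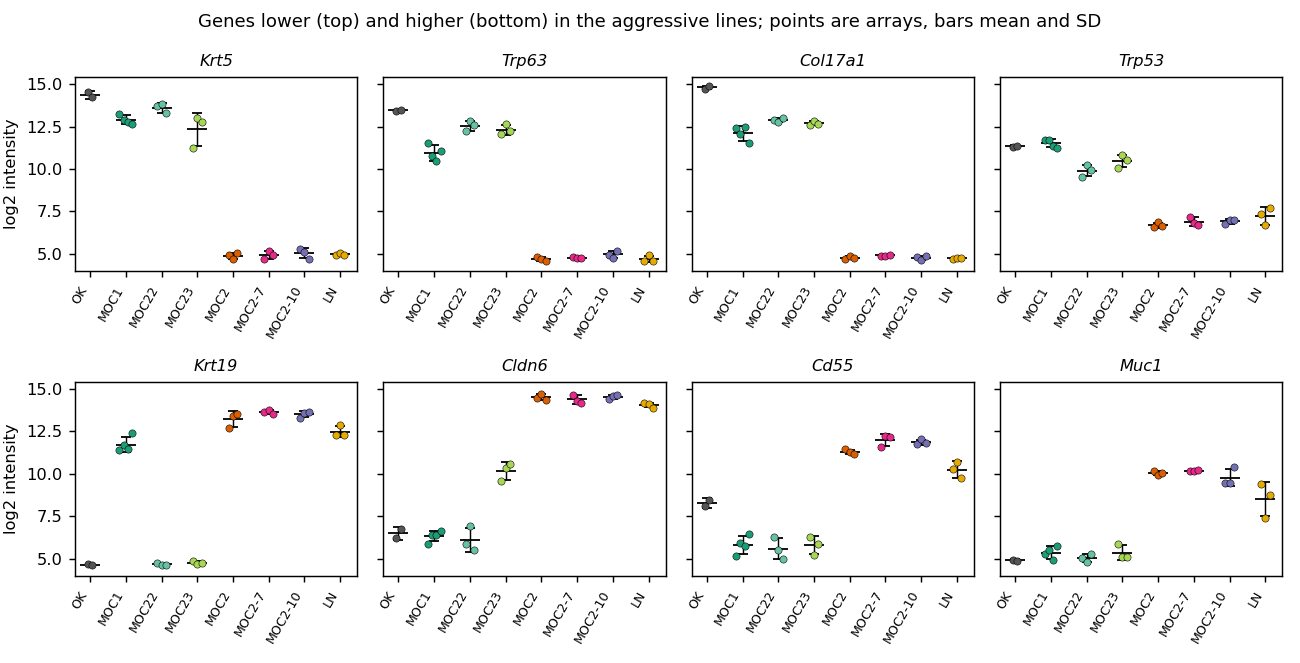
Normalized log2 intensity (y axis) of 8 genes in each line (x axis); points are arrays, and bars are the mean and SD of 2 to 4 arrays. Krt5, Trp63 and Col17a1 lie near 5 in the MOC2 family, and Krt19 is high in MOC1 as well as in the MOC2 family.

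With each line's mean as 1 unit, 3 against 3, 330 genes were called, 152 higher and 178 lower, and all 330 were among the 1154. Of 78 called genes followed by name, the largest changes and up to 4 members of each list, 39 lost the call. Of those whose change is given in the paragraphs around this one, Krt19 (adjusted p = 0.128), Cldn3 (0.373) and Egr1 (0.257) lost it, and the others, such as Trp63 (7.94e-04) and Rhox5 (0.0474), kept it. The 3 aggressive lines share 1 parent and 1 genotype label, so growth, descent and genotype cannot be told apart.

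Gene lists fixed before the data were examined were compared next. Of 18 lists tested between aggressive and indolent lines, 6 were called, all lower. Of 20 measured basal keratinocyte genes, 13 were lower, 1 higher and 6 neither, the same counts when adjusted over the list alone (camera adjusted p = 3.81e-10). Of 29 p53 targets, a list that includes Trp53 itself, 6 were lower and 23 neither, also when adjusted over the list alone (0.0118). These 2 lists were called with an estimated correlation as well (adjusted p = 0.0496 each). Fas, a death receptor, and Phlda3, an inhibitor of AKT, were p53 targets lower by -2.47 ± 0.23 (at least 2.052-fold) and -1.91 ± 0.12. Of 37 keratinocyte differentiation genes, 19 were lower, 4 higher and 14 neither (1.51e-04), with the same counts when adjusted over the list alone. NRF2 targets (9 lower, 1 higher and 19 neither of 29, and 9 lower and 1 higher adjusted over the list alone, 0.00773) included Gsta4, a glutathione transferase, at -3.85 ± 0.15. Chemokines and cytokines had 11 lower, 3 higher and 26 neither of 40, the same adjusted over the list alone (0.00773), among them Tnf, the tumour necrosis factor gene, at -3.16 ± 0.23 (at least 3.168-fold). Antigen presentation genes had 4 lower and 16 neither of 20, the same adjusted over the list alone (0.00813), among them Tapbp, a chaperone of class I loading, at -1.79 ± 0.18. These 4 lists lost the call with an adjusted p = 0.407 with an estimated correlation. The remaining 12 lists had camera adjusted p of 0.112 to 0.949. Among them, 7 of 38 epithelial junction genes were lower and 5 higher, with Dsg3, a desmosomal cadherin, at -2.27 ± 0.18 (at least 2.102-fold) and Cldn3, a claudin, at 3.27 ± 0.17 (at least 6.783-fold). The ERK pathway output list had 4 of 21 genes higher, including Egr1 and Fosl1, immediate early transcription factors, at 1.42 ± 0.23 and 1.35 ± 0.19.

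The indolent lines were compared with keratinocytes to show changes shared by lines that grow slowly. Both keratinocyte arrays carry late submitter numbers (6959 to 6963). Of the other arrays, only MOC1 replicate 4, MOC22 replicate 3 and MOC23 replicate 3 do. Whether these numbers mark a batch is not given in the labels. Genes of cornified epithelium were among the largest decreases. Cnfn, Sprr2f and Sprr2e, which encode cornified envelope proteins, changed by -6.81 ± 0.72 (at least 79.39-fold, adjusted p = 3.89e-07), -6.25 ± 0.56 (at least 45.05-fold, 3.87e-08) and -6.19 ± 0.52 (at least 56.25-fold, 1.67e-08), with n = 10 arrays against n = 2. Spp1, the matrix protein osteopontin, rose by 7.08 ± 0.39 (at least 51.79-fold, adjusted p = 3.22e-11). Cdkn2a, the locus of the cell cycle inhibitor p16, rose by 6.41 ± 0.61 and was detected on 10 of 10 indolent and 0 of 2 keratinocyte arrays, at least 34.19-fold higher.

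Of 9228 genes, 1367 were called between indolent lines and keratinocytes, 590 higher and 777 lower. The arrays did not overlap for 970 of them and for 18.9% of all genes, where chance gives 3.03% only if arrays of a line count as independent. Without the 2-fold minimum the balance turned, with 1244 higher and 1222 lower. Msln, the surface protein mesothelin, rose by 5.59 ± 0.24 (at least 25.24-fold), Thbs2, an antiangiogenic matrix protein, by 5.18 ± 0.29 (at least 14.25-fold), and Sostdc1, a secreted BMP and Wnt antagonist, by 5.26 ± 0.47. Vsig8, a membrane protein of hair and nail, changed by -7.00 ± 0.19 (at least 65.71-fold), Wfdc12, a protease inhibitor, by -6.97 ± 0.41 (at least 69.42-fold), and Krt23, a stress-induced keratin, by -6.59 ± 0.38 (at least 72.18-fold). Camera called 9 of 18 lists. Keratinocyte differentiation (28 lower, 2 higher, 7 neither of 37, camera adjusted p = 1.36e-14), epithelial junctions (16 lower, 22 neither of 38, 1.12e-09) and basal keratinocyte genes (13 lower, 1 higher, 6 neither of 20, 3.8e-08) were lower and kept the call with an estimated correlation (adjusted p = 0.0411 each). So were p53 targets (11 lower, 18 neither of 29, 9.77e-05), with an adjusted p = 0.00414 with an estimated correlation. These counts were identical when adjusted over the list alone. Cdkn1a, the p53 target that encodes p21, changed by -2.45 ± 0.32. Cholesterol synthesis (9 lower, 11 neither of 20) and NRF2 targets (8 lower, 1 higher, 20 neither of 29), with the same counts adjusted over the list alone, were lower (camera adjusted p = 3.42e-04 and 0.00298). They lost the call with an adjusted p = 0.29 and 0.391 with an estimated correlation. Mesenchymal and EMT regulators (8 higher, 4 lower, 12 neither of 24, and 9 higher and 4 lower adjusted over the list alone) were higher with a camera adjusted p = 0.029, and an adjusted p = 0.391 with an estimated correlation. Vim, the filament protein vimentin, and Twist1, a regulator of epithelial to mesenchymal change, rose by 4.99 ± 0.42 (at least 16.64-fold) and 3.16 ± 0.24 (at least 4.572-fold). The cell cycle list (2 higher, 35 neither of 37, also adjusted over the list alone, 0.00785) and the interferon response list (9 higher, 3 lower, 22 neither of 34, and 11 higher and 4 lower adjusted over the list alone, 0.0248) were higher. They had an adjusted p = 0.62 each with an estimated correlation.

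The aggressive lines were compared with the same 2 keratinocyte arrays. No aggressive array has a late submitter number, so early against late samples cannot be told from lines against keratinocytes here. A term for late numbers rests on the indolent lines, the only groups with both. With it, 17 calls of named genes were lost over all comparisons. Basal genes without detected signal in the aggressive lines were among the largest decreases. Col17a1 changed by -10.00 ± 0.18 (at least 390.9-fold, adjusted p = 3.27e-19), Krt5 by -9.45 ± 0.31 (at least 291.2-fold, 3.45e-15) and Trp63 by -8.66 ± 0.22 (at least 153.8-fold, 8.8e-17), with n = 9 arrays against n = 2. Krt16, a keratin of stressed epithelium, changed by -8.78 ± 0.87 (at least 388.1-fold). Krt19 rose by 8.83 ± 0.23 (at least 168.9-fold, adjusted p = 9.97e-17), Ankrd1, a nuclear cofactor induced by mechanical load, by 8.08 ± 0.53 (at least 137.1-fold), and Cldn6 by 7.997 ± 0.28. Vim rose by 7.30 ± 0.42 (at least 82.81-fold) and Dok2, a signalling adaptor of blood cells, by 6.80 ± 0.26 (at least 45.58-fold), both detected on 9 of 9 aggressive and 0 of 2 keratinocyte arrays.

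In this comparison 2079 genes were called, 992 higher and 1087 lower, and the arrays of 1920 did not overlap, with 40.3% of all genes not overlapping, where chance gives 3.64% under the same condition. Without the 2-fold minimum the balance turned, with 2049 higher and 1579 lower. Camera called 8 of 18 lists. Keratinocyte differentiation (31 lower, 6 neither of 37, camera adjusted p = 1.74e-17), basal keratinocyte (16 lower, 1 higher, 3 neither of 20, 1.51e-14) and p53 targets (14 lower, 15 neither of 29, 8.53e-07) kept the call with an adjusted p = 0.0224, 0.00807 and 4.4e-04 with an estimated correlation. The counts adjusted over the list alone were the same. Epithelial junctions had 17 lower, 4 higher and 17 neither of 38 (3.96e-05) and an adjusted p = 0.179 with an estimated correlation. NRF2 targets had 12 lower, 1 higher and 16 neither of 29 (7.37e-05), with an adjusted p = 0.179 with an estimated correlation. Nqo1, the NRF2 target that encodes a quinone reductase, changed by -5.73 ± 0.37 (at least 31.71-fold). Cholesterol synthesis genes (13 lower, 1 higher, 6 neither of 20) and antigen presentation genes (10 lower, 2 higher, 8 neither of 20) were lower, with camera adjusted p = 2.66e-04 and 0.00278, and an adjusted p = 0.204 and 0.292 with an estimated correlation. Cell cycle genes were higher (7 higher, 30 neither of 37, 0.00189), among them Foxm1, a mitotic transcription factor, at 1.43 ± 0.20, with an adjusted p = 0.524 with an estimated correlation. The counts of these 5 lists were the same adjusted over the list alone. Of 30 leukocyte markers on the array, only 4 passed the filter on dim probes, too few for camera. Of these 4, 3 were lower in the aggressive lines and 2 in the indolent lines, also adjusted over the list alone. Cd68, a lysosomal protein of macrophages, changed by -3.61 ± 0.62 in the aggressive and -2.60 ± 0.61 in the indolent lines. Lyz2, a lysozyme of myeloid cells, was detected on 2 of 2 keratinocyte arrays and on no array of these lines. The keratinocyte arrays alone were enough for Lyz2 to be measured.

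**Figure D3:**
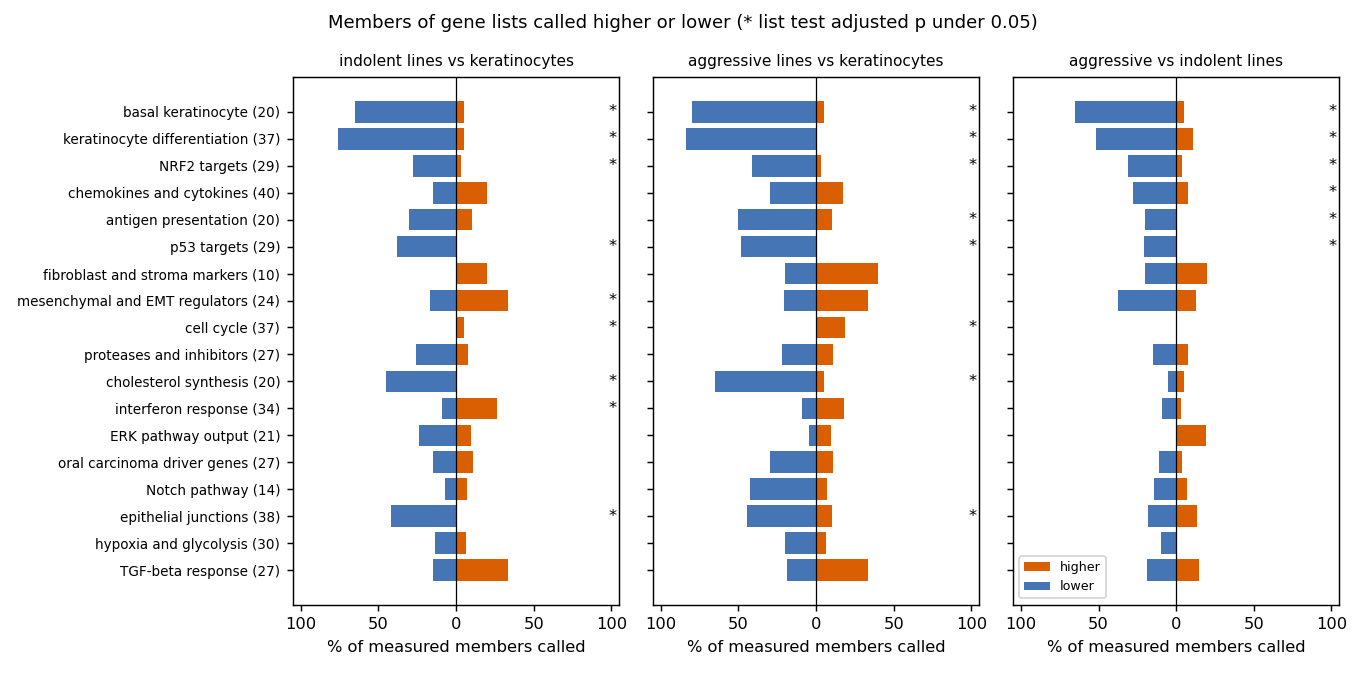
Share of each list's measured members called higher or lower (x axis, percent) for 18 gene lists (y axis, measured members in brackets) in 3 comparisons; a star marks a camera adjusted p under 0.05 with the preset correlation. The basal keratinocyte and keratinocyte differentiation lists are mostly lower in each panel.

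LN was compared with MOC2 to describe cells grown from a metastasis. LN is a single line with another genotype label than MOC2. Changes tied to metastasis therefore cannot be told from other differences between lines of MOC2 descent. MOC2-7 and MOC2-10 differed from MOC2 in 210 and 169 genes. The epithelial keratin gene Krt14 was lower in LN. It changed by -3.38 ± 0.27 (adjusted p = 1.14e-07), to a mean log2 intensity of 11.40 ± 0.56 (SD, n = 3). Epb41l3, a membrane skeleton protein, changed by -4.22 ± 0.33 (8.01e-08), Tspan8 by -3.71 ± 0.33, Tph1 by -3.50 ± 0.37 and Ppbp, a platelet chemokine gene, by -3.65 ± 0.44. Alox12, an epidermal lipoxygenase, changed by -3.81 ± 0.45. Spag6l, a protein of the axoneme, rose by 4.35 ± 0.15 (at least 8.73-fold, adjusted p = 1.86e-13), Gvin1, an interferon-induced GTPase, by 3.31 ± 0.43 (at least 3.617-fold), Bmp4, a morphogen, by 2.73 ± 0.29, and Zeb1, a repressor of epithelial genes, by 1.82 ± 0.34 (at least 1.985-fold). In all 203 genes were called, 74 higher and 129 lower, and 201 did not overlap. With only the groups compared the count was 82, and without background correction 89. Of all genes 17.9% did not overlap, where chance gives 10%. Without MOC2 replicate 1 the count was 355, with no excess of lower genes (178 higher, 177 lower). Without MOC2 replicate 2 it was 132, and without LN replicate 3 it was 129. Keratinocyte differentiation (3 lower, 34 neither of 37, and 4 lower adjusted over the list alone, camera adjusted p = 0.00749) and epithelial junctions (1 lower, 1 higher, 36 neither of 38, also adjusted over the list alone, 0.0284) were lower. Both had an adjusted p = 0.924 with an estimated correlation.

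MOC2-7 was compared with its parent MOC2. Pdpn, the membrane glycoprotein podoplanin, changed by -5.10 ± 0.20 (at least 17.6-fold, adjusted p = 7.83e-13) and Esm1, an endothelial proteoglycan gene, by -5.86 ± 0.27 (at least 21.4-fold, 1.7e-11), both detected on 3 of 3 MOC2 and 0 of 3 MOC2-7 arrays. Dhh, a hedgehog ligand, changed by -4.51 ± 0.32 (at least 9.253-fold), Plac8, a small cysteine-rich protein, by -4.36 ± 0.34, and Cdh3, the basal P-cadherin, by -2.65 ± 0.22. Ppp1r1b, a phosphatase inhibitor, rose by 4.01 ± 0.36 (at least 9.402-fold), Fgf7, a keratinocyte growth factor, by 3.69 ± 0.35 (at least 5.158-fold), Col5a1, a fibrillar collagen, by 3.20 ± 0.45 (at least 3.389-fold), and Twist2 by 2.65 ± 0.46 (at least 3.38-fold). In all 210 genes were called, 118 higher and 92 lower, and 205 did not overlap. Of all genes 13.6% did not overlap, where chance gives 10%. Without MOC2 replicate 1 the count was 537. With only the groups compared it was 64, and the balance turned to 23 higher and 41 lower. Without the third run of 8 columns it turned as well (32 higher, 38 lower). Camera called 5 lists. Epithelial junctions (3 lower, 35 neither of 38, and 4 lower adjusted over the list alone, 3.4e-07) and basal keratinocyte genes (3 lower, 17 neither of 20, and 5 lower adjusted over the list alone, 3.46e-07) were lower, with an adjusted p = 0.123 each with an estimated correlation. Keratinocyte differentiation (1 lower and 36 neither of 37, also adjusted over the list alone) was lower with a camera adjusted p = 0.0146, and an adjusted p = 0.711 with an estimated correlation. Interferon response (3 higher, 31 neither of 34, also adjusted over the list alone, 1.48e-06) was higher, with an adjusted p = 0.392 with an estimated correlation, and included Ifitm3, an antiviral membrane protein, at 1.92 ± 0.33. Antigen presentation was higher with a camera adjusted p = 0.0146, 20 of 20 members neither over all genes and 1 higher adjusted over the list alone, and an adjusted p = 0.524 with an estimated correlation.

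MOC2-10, the line with lung on its metastatic label, was compared with MOC2. All 5 measured genes of the Hoxb cluster, homeobox genes that pattern the body axis, were called higher in MOC2-10, with no detected array in MOC2. These genes passed the filter on dim probes through the MOC2-10 arrays. Outside MOC2-10, only Hoxb7 was detected, on 1 MOC1 array. A Hoxb gene not raised in MOC2-10 could have been left unmeasured, so this count does not speak for the whole cluster. Hoxb7 rose by 4.71 ± 0.22 (SE, adjusted p = 1.22e-11), from no detected array in MOC2 to 3 of 3 arrays, at least 8.93-fold. Hoxb5 rose by 2.55 ± 0.36 (1.96e-04), Hoxb6 by 2.10 ± 0.22 (4.69e-06), Hoxb4 by 1.53 ± 0.19 (3.36e-05) and Hoxb9 by 1.501 ± 0.21 (1.66e-04). Hoxb9 was detected on 2 of 3 MOC2-10 arrays. Against the detection floor of MOC2, Hoxb5 was at least 2.987-fold, Hoxb6 at least 1.796-fold, Hoxb4 at least 1.306-fold and Hoxb9 at least 1.125-fold higher, so this bound reaches 2-fold for Hoxb7 and Hoxb5 only. Hoxa5 and Hoxa7, members of another cluster, rose by 2.496 ± 0.34 (at least 2.667-fold) and 2.61 ± 0.27. These were also called higher in MOC2-7 against MOC2, Hoxa7 by 2.38 ± 0.27, and between MOC2-10 and MOC2-7 Hoxa5 and Hoxa7 differed by only -0.04 and 0.23, each with an adjusted p = 1. Nrn1, a membrane-anchored neurite growth protein, rose by 3.41 ± 0.30 (at least 4.322-fold) and Bmp4 by 2.64 ± 0.29. Esm1 changed by -5.94 ± 0.27 (at least 22.67-fold), Pdpn by -5.35 ± 0.20 (at least 18.64-fold), Plac8 by -5.02 ± 0.34 (at least 25.93-fold) and Alox12 by -4.32 ± 0.45 (at least 8.844-fold). In all 169 genes were called, 67 higher and 102 lower, and 166 did not overlap. With only the groups compared the count was 95, and without background correction 83. Of all genes 14.9% did not overlap, where chance gives 10%. Without MOC2 replicate 1 the count was 331, and the balance turned to 186 higher and 145 lower. Without MOC2 replicate 3 it was 110. Basal keratinocyte genes (3 lower, 17 neither of 20, and 4 lower adjusted over the list alone, camera adjusted p = 1.48e-04) and epithelial junctions (2 lower, 36 neither of 38, also adjusted over the list alone, 2.21e-04) were lower. Both had an adjusted p = 0.488 with an estimated correlation. Krt17, a keratin of basal and activated cells, changed by -2.04 ± 0.34.

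**Figure D4:**
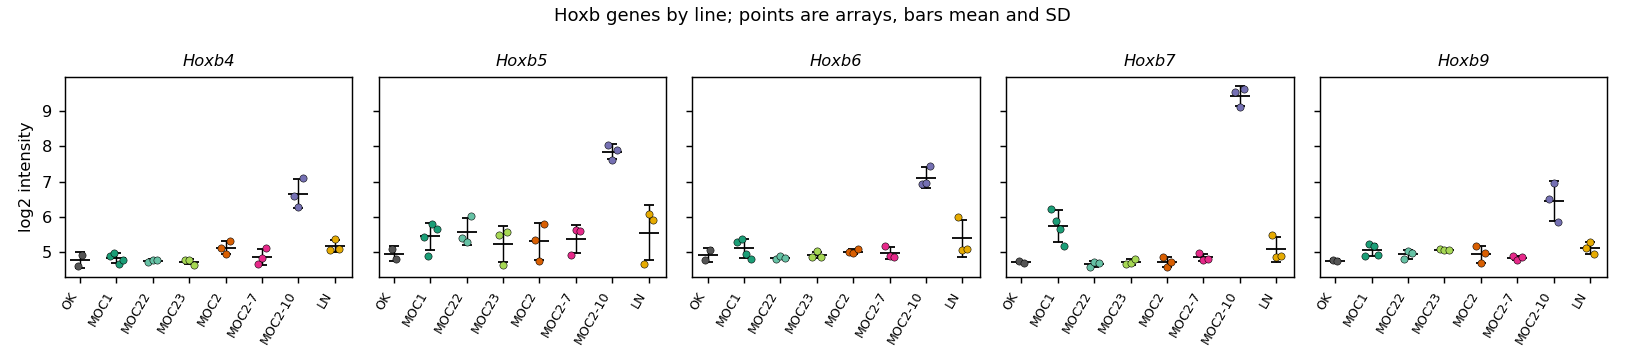
Normalized log2 intensity (y axis) of 5 Hoxb genes in each line (x axis); points are arrays, and bars are the mean and SD of 2 to 4 arrays. MOC2-10 lies above every other line for each gene.

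MOC2-10 and MOC2-7, the derivatives with different metastatic labels, differed in fewer genes. Hoxb7 was higher in MOC2-10 by 4.58 ± 0.22 (at least 9.343-fold, adjusted p = 6.18e-11) and Hoxb5 by 2.48 ± 0.36 (at least 3.126-fold, 4.55e-04). Krt27, a hair follicle keratin, was higher by 5.31 ± 0.34 (adjusted p = 5.45e-09), Bmp4 by 3.63 ± 0.29 (at least 6.788-fold), and Peg3, an imprinted zinc finger gene, by 2.71 ± 0.36 (at least 2.218-fold). Tceal8, an X-linked elongation factor homolog, was lower at -3.70 ± 0.31, Ddx25, an RNA helicase, at -3.12 ± 0.23 (at least 3.928-fold), and Bmp8b, a BMP ligand, at -2.65 ± 0.26 (at least 3.284-fold). In all 71 genes were called, 22 higher and 49 lower, and all 71 did not overlap. With only the groups compared the count was 28, and without background correction 32. Of all genes 9.6% did not overlap, no more than the 10% that chance gives. Interferon response and fibroblast and stroma markers were lower in MOC2-10, with camera adjusted p = 4.02e-06 and 1.6e-05. They had an adjusted p = 0.528 and 0.0501 with an estimated correlation. All 34 interferon members were neither, with 2 lower adjusted over the list alone, and of 10 stroma members 1 was lower and 9 neither, with 4 lower adjusted over the list alone. Antigen presentation (20 of 20 neither, 1 lower adjusted over the list alone) and NRF2 targets (29 of 29 neither, also adjusted over the list alone) were lower and epithelial junctions (2 higher, 1 lower, 35 neither of 38, also adjusted over the list alone) higher (0.00143, 0.0344 and 0.0108). These had an adjusted p = 0.528, 0.663 and 0.606 with an estimated correlation.

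Whether cells from the node and cells with a lung label shared changes was described with differences that have no array in common. Across 9228 genes, LN minus MOC2 and MOC2-10 minus MOC2-7 correlated with Pearson r = -0.086 and Spearman rho = -0.131. Genes are not independent replicates. Leaving out 1 array at a time gave Pearson values from -0.257 without MOC2-7 replicate 3 to 0.069 without MOC2-10 replicate 3, so the sign was not stable.

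The indolent lines also differed from each other. The counts here are for single lines, so they cannot be set against the 1367 genes between the mean of the indolent lines and keratinocytes. Group means of indolent lines correlated with r = 0.9254 to 0.9307 with each other and 0.8865 to 0.9091 with the keratinocytes. MOC22 against MOC1 gave 1368 called genes (650 higher, 718 lower), MOC23 against MOC1 1589 (786 higher, 803 lower, and 403 higher and 362 lower without background correction) and MOC23 against MOC22 1258 (658 higher, 600 lower). MOC22 carried less Cldn3 (-8.15 ± 0.29, at least 97.92-fold), Krt7, a simple epithelial keratin (-7.25 ± 0.25), and Krt19 (-7.07 ± 0.23, at least 45.64-fold) than MOC1, and more Cd80, a T cell costimulator (5.80 ± 0.26), Kcnab2, a potassium channel subunit (5.40 ± 0.24), and Gria3, a glutamate receptor (5.12 ± 0.34, at least 20.36-fold). MOC23 carried less Pdpn (-8.75 ± 0.18, at least 255.8-fold), Krt19 (-6.98 ± 0.23, at least 49.79-fold) and Plac8 (-6.96 ± 0.32) than MOC1, and more Nrn1 (6.95 ± 0.28, at least 46.52-fold), S100a8, a calprotectin subunit (5.86 ± 0.64), and Cyba, an oxidase subunit (4.97 ± 0.34). Against MOC22, MOC23 carried more Gsta3, a glutathione transferase (7.17 ± 0.62), and Nrn1 (6.96 ± 0.30, at least 43.54-fold), and less Sncg, a synuclein (-7.16 ± 0.47, at least 90.78-fold), Pdpn (-7.05 ± 0.20, at least 78.79-fold) and Mmrn2, an endothelial matrix protein (-6.45 ± 0.25, at least 34.21-fold). Cd44 was higher in MOC22 than in MOC1 by 1.72 ± 0.26 and lower in MOC23 than in MOC22 at -2.56 ± 0.28.

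Among the lists, p53 targets were higher in MOC22 than in MOC1 (12 higher, 1 lower, 16 neither of 29, also adjusted over the list alone, camera adjusted p = 0.00291) and kept the call with an adjusted p = 0.0123 with an estimated correlation. Trp53 itself was lower there at -1.62 ± 0.23. Epithelial junctions were lower in MOC22 than in MOC1 (10 lower, 1 higher, 27 neither of 38, also adjusted over the list alone, 0.036), with an adjusted p = 0.958 with an estimated correlation. Keratinocyte differentiation was higher in MOC23 than in MOC1 (14 higher, 3 lower, 20 neither of 37, and 16 higher and 3 lower adjusted over the list alone, 0.0442) and than in MOC22 (18 higher, 3 lower, 16 neither, also adjusted over the list alone, 3.29e-04). The adjusted p was 0.812 and 0.752 with an estimated correlation. NRF2 targets were higher in MOC23 than in MOC1 (10 higher, 19 neither of 29, also adjusted over the list alone, 0.0464), among them Nqo1 at 3.04 ± 0.37, with an adjusted p = 0.812 with an estimated correlation.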

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

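The tests of the 3 patterns below were all chosen after the result was seen; the splits of arrays and lines were planned, except the list counts for MOC2-10 against MOC2-7 and between indolent lines, which were added afterwards. In MOC1, the group with 4 arrays, 275 values were tested: the named genes, median intensity, probes detected and mean beads per probe. Of these, 14 had 1 array far from the others by Dixon's test (5.09%, where about 5% pass by chance), all of them genes. Replicate 4 stood apart for Aldh3a1 (12.44), Col4a1 (11.37), Flt1 (9.96) and Ifi47 (7.59). Replicate 1 stood apart for Ccl2 (6.55), Chst1 (5.27), Id2 (6.89), Itga6 (9.70), Mmp10 (7.11) and Peg3 (6.66), and replicate 2 for Fgfr2 (6.04), Sprr2e (5.44) and Wfdc12 (5.26), all in log2 intensity.

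Against keratinocytes, 25 genes were called in opposite directions in indolent and aggressive lines. The named ones, with the limma difference of aggressive minus indolent lines, were Cd55 (6.00), Nkx2-3 (5.35), Gpx2 (-7.67), Ppbp (-3.32), Sh3tc2 (-4.36) and Tnc (-4.52). Against MOC2, 3 genes were called in opposite directions in MOC2-7 and MOC2-10, with a difference of MOC2-10 minus MOC2-7 of 5.31 for Krt27, -3.12 for Ddx25 and -3.01 for Sh3tc2.

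Trp63 had no detected signal in any line of MOC2 descent, and 13 of 20 basal genes were lower in the aggressive lines. Loss of a segment that holds Trp63 and the 3 nearest genes on each side is argued against, counting genes detected on all indolent arrays. These neighbours were detected on 9 of 9 aggressive arrays with a median log2 change of 0.15. Bcl6, the nearest of them on 1 side, changed by -1.56, so a loss that reaches from Trp63 to Bcl6 stays open. Dimmer genes were passed over, and a loss at Trp63 alone stays open. A median above -1 does not test a loss in part of the copies or cells. The rule for this median replaced one that required every neighbour to stay above -1, which Bcl6 had failed. Replacement by non-epithelial cells is argued against as well, since 3 of 38 epithelial junction genes fell by as much as the basal list's median of -1.48 (also 3 at -1.34, with undetected lines at their bound). Common descent stays open: all 4 groups without Trp63 signal descend from MOC2 and 0 others lacked it, so descent and growth cannot be told apart.

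Arrays of a line differed, in MOC1 and the MOC2 family, along an axis that held 35% of the within-line variance. The run of 8 columns in the scanner table explained 19.6% of it (permutation p = 0.202), the cell cycle list lay at percentile 16.2 of random lists, and the more 5′ probe of a transcript moved further in 49.4% of 1344 transcripts (95% interval 46.7 to 52.1), so position, growth state and RNA breakdown stay open. Scores on this axis reached 40.78 in MOC2. They ran only from -3.85 to 4.17 in MOC22, -3.26 to 2.73 in MOC23 and -1.74 to 1.74 in the keratinocytes. Loadings correlated with gene length (Spearman 0.261 across genes), so a signal that depends on length could be a source. A second axis, with 23.8% of the variance, was explained at 78.5% by the column run (permutation p = 1e-04, the smallest the permutations can give), so array position may be its cause. Apart from growth state, no biological explanation was tested.

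Genes of single chromosomes were shifted together in 92 of 160 pairs of a group and a chromosome (adjusted permutation p under 0.05), at most at chromosome 7 in MOC23 (median -0.57 log2), relative to the lines of other origin. Chromosome 8 was shifted by 0.45 in MOC2, 0.39 in MOC2-7 and 0.35 in MOC2-10, by only 0.17 in LN of the same descent, and by -0.335 in MOC22. All 4 equal parts of the chromosome moved to the same side in 10 of 10 pairs of a tumour line shifted by at least 0.3. This was also so in 12 of 12 shifted pairs of the normal keratinocytes, at shifts of up to 0.26. Each group was set against the mean of the groups of other origin. A shift in a tumour line therefore enters the keratinocytes and the other lines with the opposite sign. The 92 pairs are thus not independent, and the keratinocytes are no independent control. Neither count decides on a change in copy number, which stays open. DNA was not analysed here, and the minimum shift and the look at keratinocytes were chosen after the shifts were seen.

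Other splits of the same arrays were counted for comparisons with at least 3 arrays on each side, so not for those with keratinocytes. For aggressive against indolent lines, 1 of 100 splits of the arrays (the real one) gave as many genes, 994 in the fit of 2 groups beside at most 486. The other splits could put arrays of a line on both sides, which adds line differences to the spread and favours the real split. This count therefore decides nothing about chance among lines. For lists, 16 of 100 gave the real 6 or more, up to 9, so chance cannot be excluded. For MOC22 and MOC23 against MOC1, 1 of 35 splits gave as many genes (1368 beside at most 922, and 1589 beside at most 932). This excludes chance for genes only if arrays of a line count as independent. For their lists, 28 of 35 gave the real 2 or more, up to 8, and 29 of 35 the real 2 or more, up to 11. Chance cannot be excluded there. The other comparisons counted had 10 splits, too few for a share under 0.05. With lines as units, 1 gave 1154 genes (the others at most 597) and 1 gave 6 lists (at most 5). For LN against MOC2, 1 gave 203 genes (at most 0, with 1775 at an unadjusted limma p under 0.05) and 5 gave 2 or more lists (at most 5). MOC2-10 against MOC2-7 had 1 split with 71 genes (at most 0, with 747 at an unadjusted limma p under 0.05) and 5 with 5 or more lists (at most 7). MOC23 against MOC22 had 1 with 1258 genes (at most 137) and 10 with 1 or more lists (at most 5). For MOC2-7 against MOC2, 2 splits gave 210 or more genes, up to 772, and 5 gave 5 or more lists (at most 6). For MOC2-10 against MOC2, 2 gave 169 or more genes, up to 590, and 8 gave 2 or more lists (at most 6). Both larger splits put replicates 1 and 2 of the derivative with MOC2 replicate 1, arrays on the positive side of the first within-line axis. The real counts lie below that structure, and without MOC2 replicate 1 they were 537 and 331. With the runs of 8 columns as a block they were 256 and 184.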

How the results depend on the processing

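The runs of 8 columns, the third run left out, array weights and the arrays left out of the correlation were chosen after the results were seen. Of 14665 combinations of a named gene's comparison and an alternative, 13904 kept direction and call, 752 kept the direction without the call, 7 were newly called and 2 reversed: Col5a1 (-0.085) and Angptl4 (0.33) with MOC2 as the only aggressive line. The call was kept under every alternative chosen beforehand for 364 of 562. Counts are given in the order aggressive against indolent (1154), indolent (1367) and aggressive (2079) against keratinocytes, LN (203), MOC2-7 (210) and MOC2-10 (169) against MOC2, MOC2-10 against MOC2-7 (71), MOC22 (1368) and MOC23 (1589) against MOC1, and MOC23 against MOC22 (1258). Without background correction, which leaves a constant that shrinks every ratio, they were 527, 757, 1220, 89, 111, 83, 32, 711, 765 and 706. Without a fold minimum, which only adds genes, the first 3 were 4015 (2255 higher, 1760 lower), 2466 and 3628 and the last 3 were 2645, 3058 and 2080. With only the groups compared, which leaves fewer arrays for the spread, LN gave 82, MOC2-7 64, MOC2-10 95 and the derivatives 28. Line means gave 330 from 6 units. Without the third run of columns, again fewer arrays, LN gave 100, MOC2-7 70, MOC2-10 98 and the derivatives 36. Array weights gave 613 (360 higher, 253 lower), 1050 and 1183 (870 higher, 313 lower) against MOC2, which turned the balance for LN and MOC2-10, with weights of 0.328 to 5.8. That weight estimate stopped before convergence, so these counts rest on an unfinished estimate, and the cause of the increase was not tested. Over arrays left out in turn, the counts ran from 1118 to 1199, 999 to 1407, 1783 to 2172, 129 (without LN replicate 3) to 355, 141 to 537, 110 (without MOC2 replicate 3) to 331, 52 to 68, 1243 to 1508, 1335 to 1817 and 1158 to 1377. The highest for LN, MOC2-7 and MOC2-10 came without MOC2 replicate 1, and LN gave 132 without MOC2 replicate 2. Scaling to the 75th percentile and the authors' values kept every gene count within 1.5 times. Called lists with an estimated correlation numbered 2, 4 and 3 for the first 3 comparisons and 0 each for LN, MOC2-7 and MOC2-10, where 0, 2 and 1 had an unadjusted p under 0.05. With fry they were 11, 10 and 14, then 0 for LN (1 at an unadjusted p under 0.05), 2 for MOC2-7 and 1 for MOC2-10. The cause was not tested. The correlation of LN minus MOC2 with MOC2-10 minus MOC2-7 (-0.086) ran from -0.257 to 0.069 over arrays left out, with 0.032 without MOC2-7 replicate 1, and was 0.109 without the third run. Whether replicate numbers pair the arrays stays open: 35 of 77 same-number pairs correlated over 0.1, and 12 of 24 arrays correlated best with their own number. The median correlation was 0.049 for same-number pairs and -0.035 for other pairs. The values that chance gives were not computed. The replicate block gave 1143, 1353, 2060, 206, 230, 177, 73, 1514, 1746 and 1255 genes and 6, 9, 8, 3, 5 and 2 lists.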

Other observations

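Trp53 had a mean log2 intensity of 6.69 ± 0.15 (SD, n = 3) in MOC2, 6.90 ± 0.25 (n = 3) in MOC2-7, 6.90 ± 0.15 (n = 3) in MOC2-10 and 7.25 ± 0.53 (n = 3) in LN, beside 11.33 ± 0.06 (n = 2) in the keratinocytes. Of its nearest neighbours detected on all indolent arrays, Trappc1, Kdm6b, Wrap53, Mpdu1 and Eif4a1 changed by 0.04, -0.02, 0.56, 0.15 and 0.29 between aggressive and indolent lines. Sox15, also among them, changed by -3.05. It was detected on only 2 of 9 aggressive arrays, so the size of this change depends on the offset and is not exact. Around the Hoxb genes raised in MOC2-10, the 8 nearest flanking genes with a mean log2 intensity above 8 changed by -0.62 to 0.63 against MOC2, with limma adjusted p of 0.481 to 0.98.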
